A study of Drosophila melanogaster with 3 samples.

How the data were processed

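Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Drosophila melanogaster embryos collected over 0 to 24 hours, with both sexes pooled. The flies carried a MiMIC insertion, a transposon cassette exchanged for an eGFP exon inside an intron of the mam gene, so that the Mastermind (Mam) protein was made as a fusion with eGFP. Per the labels, chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP. The series held 1 group, Mam-GFP embryos, with 3 samples that the labels number as biological replicates 1 to 3. The labels name a possible control, which was not analysed here.

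The authors deposited peak lists in 2 genome builds, dm6 and dm3. Per the notes deposited with the samples, each replicate had a list of peaks and background made as input for the irreproducible discovery rate (IDR) procedure, which keeps peaks ranked alike in replicates. A list of the same kind covered the pooled replicates, and an IDR-thresholded list was derived from these. The aligner, the peak caller, their versions and the thresholds are not given in the sources used here. Each peak carried the authors' signal value, a peak height that is never negative and whose scaling is not stated in the deposited notes. It also carried the authors' −log10 q-value, which reached at most 4.00 in the pooled dm6 list and was at that highest value for 94.7% of the IDR-thresholded peaks. Peaks were therefore ranked by signal, within a list only. The 5326 IDR-thresholded dm6 peaks, called reproducible peaks below, were identical to the 5326 strongest of the 24073 pooled peaks. In dm3 the numbers were 5027 and 22406. The replicate lists held 30000, 24267 and 24306 peaks in dm6, and whether the first was cut at a set number is not given in the sources used here. Because these lists include background calls, replicates were compared through their 5326 strongest peaks. Read numbers are not given in the peak lists, so the depth of each sample is unknown. Exact binomial (Clopper-Pearson) 95% intervals of shares cover counting error only.

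The reference was the Release 6 assembly (the dm6 sequence) with the Ensembl 115 annotation (BDGP6.54), which held 13968 protein-coding genes and 19630 transcription start sites (TSSs) on the main chromosome arms. No peak of the dm6 lists ended beyond its arm. Positions are 1-based dm6 coordinates. The dm3 lists were used only for overlaps and chromosome shares. All names of the 22 gene lists, fixed before the data were examined, were matched, 4 of them through synonyms in the annotation and 2 through current symbols assigned by hand (Delta and nanos).

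Support of the reproducible peaks was the share overlapped by at least 1 bp by the 5326 strongest peaks of each replicate, set beside 100 shuffles within chromosomes. Summits per chromosome arm were compared with the share of sequenced bases by exact binomial tests. Summits were classed as promoter (within 500 bp of a TSS), 5' UTR, coding sequence, 3' UTR, intron or intergenic, in that order of precedence, and compared with 53260 random positions on the same arms by Fisher's exact test. A gene counted as carrying a peak when a reproducible summit lay within 1000 bp of one of its TSSs, and each gene list was compared with all other protein-coding genes by Fisher's exact test. For the 9 lists with at least 5 such genes, the median of the strongest signal was tested with 100000 permutations. The 19 sequence motifs were searched on both strands within 100 bp of the summit and in an equal window 1000 bp away on a random side, and compared by the exact McNemar test. An exploratory run of this test with another random choice of sides preceded the run reported, and the sides of the reported run were not chosen for its result. The reversed motif served as a control for base composition. The signal ranks of peaks with and without a Su(H) site were compared with 100000 permutations. All tests were two-sided, and Benjamini-Hochberg adjustment was applied within each family, with a threshold of 0.05. Peaks and genes of a list are not biological replicates, so these p-values measure the spread over peaks or genes. The mean and SD of the same quantity in the strongest peaks of the 3 replicates are given beside them. Nothing in the labels gives batches or dates of the samples.

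Named genes followed a rule set before the data were examined. It took mam, every member of both Notch lists, the gene with the nearest TSS for the 20 strongest reproducible peaks, up to 4 members of every other list with the highest signal, and the 5 genes with the most summits in the gene and 5000 bp around it. Alternatives set at the same time were other overlap rules, list lengths, windows and backgrounds, the dm3 lists, the 2663 strongest peaks alone, leaving out peaks with over 50% of soft-masked (repeat) sequence, and leaving out each replicate in turn. Leaving out a replicate kept the reproducible peaks that overlapped the strongest peaks of both others, which is a stricter set. Alternatives added after the data were seen were merging of summits closer than 500 bp, random positions matched on G+C content, and the paired window on the other side of the summit.

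Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9. The procedures were tested on simulated data. With 30% of 13968 genes bound at random, 3 lists raised to 75% were called in 98.7% of simulated lists, 3 lists lowered to 3% in 98.5%, and unchanged lists in 1.04%. The raised lists were the ribosomal protein, cell cycle and Polycomb and Trithorax group genes. The lowered ones were the cuticle protein, receptor and neural genes, and all 6 are also called below. Smaller differences, such as those of the Notch lists, were not simulated. A site planted in 10% of 3000 random windows was called, and 0 of the other motifs were. Overlap rules recovered the 60% of 1000 simulated peaks that were planted as shared.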

Results

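Mastermind is a nuclear coactivator that joins the Notch intracellular domain and the DNA-binding protein Suppressor of Hairless, Su(H), at Notch target genes. The data were genomic positions enriched by an anti-GFP precipitation from embryos making Mam-GFP, in 3 biological replicates of 1 group. The design therefore gave no contrast between conditions. It posed the questions of how well the replicates matched, where the peaks lay, which genes carried them and which sequence motifs they held. All enrichments are relative to the rest of the genome, and signal is the authors' peak height.

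The replicates shared most of their strong peaks. Of the 5326 reproducible peaks, 88.8% ± 2.03 (SD, n = 3) were overlapped by the 5326 strongest peaks of a replicate. The shares were 86.5%, 89.5% and 90.3% for replicates 1, 2 and 3, and shuffled peaks gave at most 3.59%. The reproducible peaks came from the pool of these same replicates, so high support is partly built in. The shuffles show only the overlap of randomly placed peaks, and the pairwise overlap below is free of the pooled list. All 3 replicates supported 3917 peaks, 2 supported 1034, 1 supported 364 and none of them supported 11. Of the 2663 strongest reproducible peaks, 2651 were supported by all 3 replicates, against 1266 of the 2663 weakest. Pairs of replicates shared 81.7% ± 2.85 (SD over the 3 pairs) of their strongest peaks, from 79.4% for replicates 1 and 2 to 84.9% for replicates 2 and 3.

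The strongest peaks lay near genes of many kinds. The strongest of all, with a signal of 5297, lay on chromosome 3L at 19590400 to 19590826, with its summit in the promoter class 97 bp from a TSS of the uncharacterised gene CG14100. The next was an intronic peak on 2L (480846 to 481328, signal 5028), within the gene ush and 1402 bp from the nearest TSS. That TSS belongs to cbt, which encodes a zinc finger transcription factor. After it came a promoter peak of Ugalt (X, 2703681 to 2704118, signal 4964), which encodes a UDP-galactose transporter. Peaks nearest to mRpL41, a mitochondrial ribosomal protein gene (signal 3903), CG11050 (3712) and the Polycomb group gene ph-p (3154) followed. Then came those nearest to the chromodomain gene Chro (3140), the tubulin acetyltransferase gene Atat (3061), the kinase gene Lk6 (2969) and px (2941). The peaks ranked 11 to 20 were nearest to CG4004, Tcs5, PNPase, CG32772, HmgZ, CG9663, larp, GstE13, CG1888 and CenG1A. All 20 were supported by 3 replicates, 13 were in the promoter class, and ph-p was the 1 nearest gene of the 20 that belonged to a list.

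Summits were concentrated at promoters and nearly missing from coding sequence. Promoters held 2906 of 5326 summits, 54.6% against 11.5% of random positions, a ratio of 4.76, and 54.8% ± 1.29 (SD, n = 3) of the strongest summits of the replicates. Coding sequence held 9 summits, 0.169% against 14.3% of random positions, a ratio of 0.0118, and 0.232% ± 0.0574 (SD, n = 3) in the replicates. For both classes the Fisher's exact p was below what the software represents accurately. The 3' UTR held 0.695% against 4.63% (Fisher's exact test, adjusted p = 6.21e-60), introns 31.2% against 38.9% (adjusted p = 2.16e-28) and intergenic sequence 12.9% against 29.9% (adjusted p = 2.14e-174). The 5' UTR held 24 summits, 0.451% against 0.813% (Fisher's exact test, adjusted p = 0.00313), a difference that was lost against random positions of the same G+C content (ratio 0.857, adjusted p = 0.591), a background chosen after the data were seen. In the replicates, introns held 30.9% ± 0.940, intergenic sequence 12.7% ± 0.246, the 3' UTR 0.739% ± 0.0287 and the 5' UTR 0.544% ± 0.135 of the strongest summits (SD, n = 3). The 5' UTR ratio was 0.369 with the 2663 strongest peaks, 0.238 with a promoter window of 1000 bp and 0.359 against the weaker pooled peaks, the 3' UTR ratio against these was 0.278, and the coding ratio was 0.0332 against the G+C-matched positions. A check without a promoter class was made after the main results were seen. Its ratios to random positions were 1.02 for introns, 1.40 for intergenic sequence and 2.78 for the 5' UTR. The lower shares of these classes therefore depended on promoters taking precedence, while coding sequence (ratio 0.0296) and the 3' UTR (0.275) stayed lower. The median distance from a reproducible summit to the nearest TSS was 345 bp, against 4230 bp for random positions. The promoter share was 65.9% in the strongest 1066 peaks and 45.2% in the weakest. The promoter ratio was 8.29 with a window of 200 bp, 3.15 with 1000 bp, and 2.10 against the 18747 pooled peaks that missed the reproducibility threshold.

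**Figure D1:**
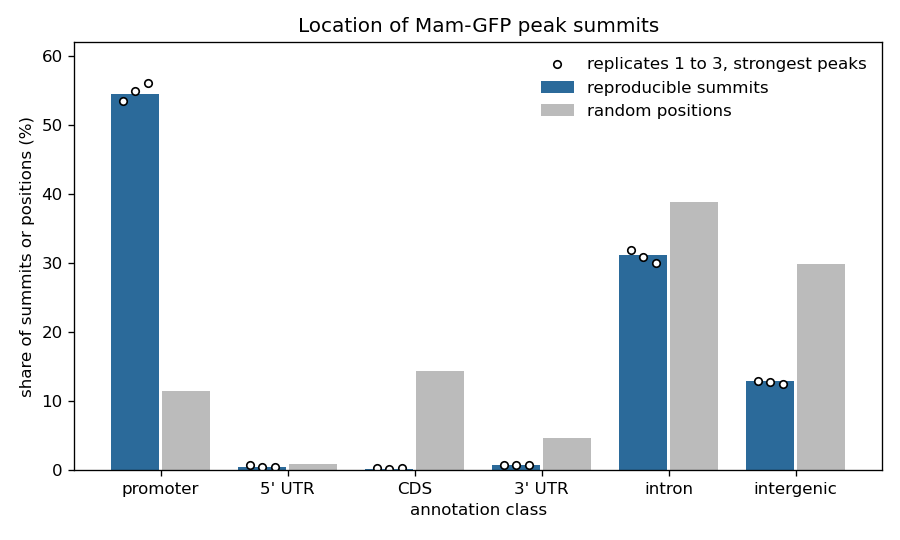
Share of reproducible summits (blue bars) and of random positions on the same arms (grey bars) in each annotation class, in percent, with the share among the 5326 strongest peaks of each replicate as open circles. Promoters held 54.6% of summits against 11.5% of random positions, and coding sequence (CDS) 0.169% against 14.3%.

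Among the chromosome arms, the X held more summits than its sequence and the fourth chromosome fewer, while the Y could not be judged. The X carried 1046 summits, 19.6% against 17.1% of the sequenced bases (ratio 1.15, exact binomial test, adjusted p = 5.99e-06), and 19.7% ± 0.710 (SD, n = 3) of the strongest summits of the replicates. Chromosome 4 carried 31 summits, 0.582% against 0.971% (ratio 0.599, exact binomial test, adjusted p = 0.00601), and 0.532% ± 0.0711 (SD, n = 3) in the replicates. The Y carried none of the summits, with 2.49% of the sequenced bases (exact binomial test, adjusted p = 6.31e-58), but how much of it could be mapped is not given in the sources used here. None of the lists, background calls included, held a peak on the Y, so the outcome of its test was fixed by what the lists cover. The bases of the Y were part of the total, which raises the ratios of all other arms somewhat. The tests were not repeated without the Y. Arms 2L, 2R, 3L and 3R had ratios of 1.04, 0.991, 0.979 and 1.01, and none of them passed the test. When the share of protein-coding TSSs replaced that of bases, the X ratio was 1.17 (exact binomial test, adjusted p = 7.63e-07), chromosome 4 no longer passed (ratio 0.805, adjusted p = 0.300) and 2R was lower (ratio 0.889, adjusted p = 0.000106).

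The tagged gene mam itself carried 2 reproducible summits within 1000 bp of its TSSs on 2R. The stronger (13991114 to 13991509, signal 166, rank 3267) lay in the promoter class 109 bp from a TSS and was supported by 3 replicates. Of the 27 Notch pathway components, 14 carried a peak, 51.9% (95% interval 31.9% to 71.3%) against 29.6% of other protein-coding genes. This difference did not pass the test (ratio 1.75, Fisher's exact test, adjusted p = 0.0505). It passed without replicate 1 (ratio 1.83, adjusted p = 0.0372) but not without replicate 2 (1.67, adjusted p = 0.140) or 3 (1.69, adjusted p = 0.168, all by Fisher's exact test). The ratio was 1.41 against matched random lists (permutation adjusted p = 0.236), 1.40 with a window of 5000 bp (Fisher's exact test, adjusted p = 0.127) and 1.42 with summits counted anywhere in the gene (adjusted p = 0.202). In the replicates the share was 53.1% ± 13.0 (SD, n = 3) against 29.4% ± 0.915 of other genes, higher in 3 of 3. The strongest of these peaks were at gro, which encodes the Groucho corepressor (3R, 26042349 to 26042667, signal 934), aph-1, a subunit of gamma-secretase (2L, 2765890 to 2766088, signal 649), numb, an inhibitor of Notch (2L, 9449499 to 9449759, signal 465), and the Mediator subunit gene skd (3L, 21027781 to 21027977, signal 388). The acetyltransferase gene nej carried 3 summits, with a highest signal of 345. Peaks also lay at CtBP (249), neur (226), pen-2 (226), Su(H) (185), the receptor gene N (177), Cdk8 (149), dx (130) and bib (114), where the number is the signal of the strongest peak. No reproducible summit lay within 1000 bp of a TSS of CycC, Delta, H, Nct, O-fut1, Psn, Ser, fng, kto, kuz, mib1, sca or spdo.

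Of the 24 Notch target genes, 4 carried a peak, 16.7% (95% interval 4.74% to 37.4%) against 29.7% of other genes, which did not pass the test (ratio 0.561, Fisher's exact test, adjusted p = 0.301). In the replicates the share was 12.5% in each of the 3, against 29.5% ± 0.932 (SD, n = 3) of other genes. Without replicate 2, in the stricter set of peaks that both other replicates supported, the list was lower (ratio 0.170, Fisher's exact test, adjusted p = 0.0430), but it did not pass without replicate 1 (0.315, adjusted p = 0.110) or 3 (0.345, adjusted p = 0.184). The ratio was 0.912 with a window of 5000 bp (Fisher's exact test, adjusted p = 0.797) and 0.714 against matched random lists (permutation adjusted p = 0.695). The 4 genes were E(spl)m3-HLH (3R, 26021282 to 26021381, signal 442, 445 bp from its TSS, 3 replicates), E(spl)mbeta-HLH (3R, 26006067 to 26006462, signal 152, 1 replicate), E(spl)m7-HLH (3R, 26036442 to 26036837, signal 149, 2 replicates) and aos (3L, 16483599 to 16483994, signal 114, 2 replicates). The E(spl)-HLH genes encode basic helix-loop-helix repressors that respond to Notch, and aos encodes an EGFR ligand inhibitor. A Su(H) site within 100 bp of the summit was present in the E(spl)mbeta-HLH peak and in none of the other 3. No reproducible summit lay within 1000 bp of a TSS of E(spl)m2-BFM, E(spl)m4-BFM, E(spl)m5-HLH, E(spl)m6-BFM, E(spl)m8-HLH, E(spl)malpha-BFM, E(spl)mdelta-HLH, E(spl)mgamma-HLH, BobA, Brd, Hey, Him, Ocho, Tom, ct, dpn, her, rst, sim or wor. With summits counted anywhere in the gene or within 1000 bp of it, 7 of the 24 genes carried one (ratio 0.799, Fisher's exact test, adjusted p = 0.777). From E(spl)mdelta-HLH to the end of gro (3R, 25997621 to 26049911), 7 reproducible summits lay in 52291 bp, 2 of them at gro. This density of 1.34 summits per 10 kb compares with 0.389 over the genome, and the difference was not tested. The strongest between the E(spl) genes (26008995 to 26009190, signal 458) was 1796 bp from the TSS of E(spl)malpha-BFM.

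**Figure D2:**
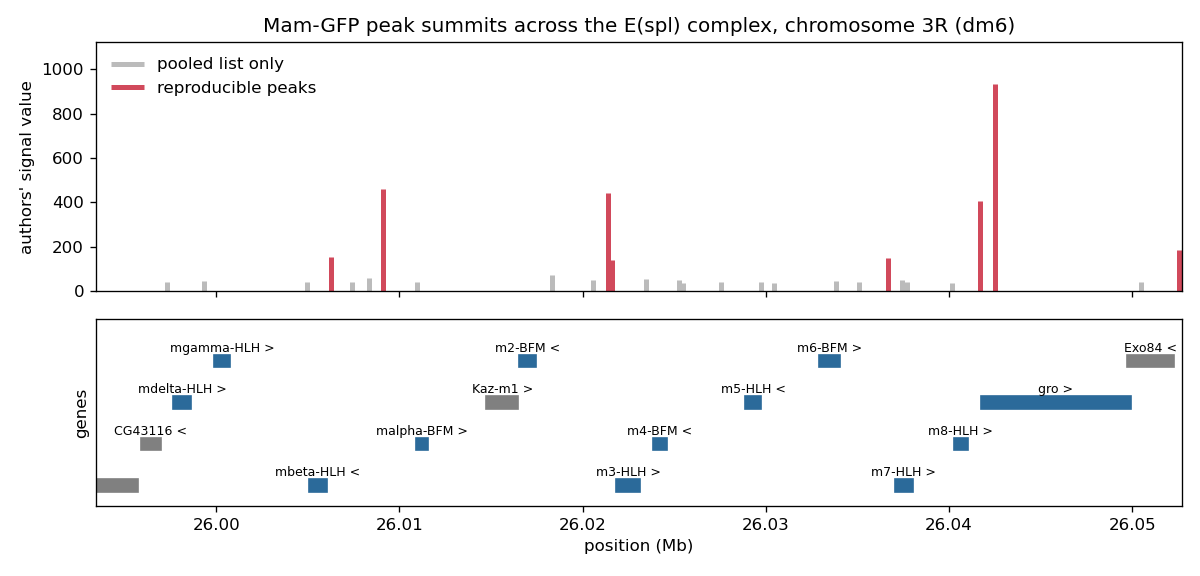
Peak summits across the E(spl) complex on chromosome 3R, with position in Mb (dm6) on the horizontal axis and the authors' signal value on the vertical axis of the upper panel. Red lines are reproducible peaks and grey lines pooled peaks below the reproducibility threshold. The lower panel shows genes, without the E(spl) prefix and with their direction, E(spl) genes and gro in blue and others in grey. The highest line, at 934, lies in gro.

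Across all 22 lists, 4145 of 13968 protein-coding genes, 29.7%, carried a peak, and 7 lists differed from other genes, 3 higher and 4 lower. Peaks lay at 69 of 92 ribosomal protein genes or 75.0% (ratio 2.55, Fisher's exact test, adjusted p = 6.38e-18), with 73.9% ± 3.92 (SD, n = 3) in the replicates. The highest signals among them were at RpL32 (1325), RpS27 (1097), RpL23A (912) and RpL34b (904), and 21 of the 69 genes had a DRE site in their strongest peak. Polycomb and Trithorax group genes, which encode chromatin regulators that maintain Hox expression, had 15 of 21 or 71.4% (ratio 2.41, Fisher's exact test, adjusted p = 0.000513) and 69.8% ± 7.27 in the replicates. Their highest signals were at ph-p (3154), Trl (822), brm (627) and ph-d (462). The cell cycle list had 13 of 24 genes or 54.2% (ratio 1.83, Fisher's exact test, adjusted p = 0.0401) and 55.6% ± 2.41 in the replicates, with dup (454), aurA (428), Mcm2 (308) and polo (290) highest. The cell cycle call was lost against random lists matched on gene length and number of TSSs (ratio 1.44, permutation adjusted p = 0.236) and with a window of 5000 bp (ratio 1.41, Fisher's exact test, adjusted p = 0.140).

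The 4 lists called lower were cuticle protein, odorant and gustatory receptor, trypsin-like protease and neural regulator genes. Peaks lay at 1 of 95 cuticle protein genes (1.05%, Fisher's exact test, adjusted p = 1.02e-12), the 1 being Cpr73D (signal 238). They lay at 3 of 119 odorant and gustatory receptor genes (2.52%, Fisher's exact test, adjusted p = 2.41e-13), namely Or88a (226), Gr32a (164) and Gr63a (139). Trypsin-like and digestive protease genes had 1 of 27 (3.70%, Fisher's exact test, adjusted p = 0.00461), Jon65Ai (125). That last call was lost when neighbouring members were merged (ratio 0.198, Fisher's exact test, adjusted p = 0.0884) and against matched random lists (ratio 0.258, permutation adjusted p = 0.251). Of the 29 neural regulators, most of them transcription factors of the nervous system, 1 carried a peak (3.45%, Fisher's exact test, adjusted p = 0.00342). It was elav, an RNA-binding protein gene of neurons, with a signal of 996. In the replicates these 4 lists had 1.40% ± 0.608, 2.24% ± 0.485, 2.47% ± 2.14 and 4.60% ± 1.99 (SD, n = 3), all lower than other genes in 3 of 3 replicates. With a window of 5000 bp the 4 lists, in the same order, were still called lower but by less. Their ratios were 0.250, 0.316, 0.515 and 0.342, against 0.0352, 0.0843, 0.125 and 0.116 with 1000 bp. With the 2663 strongest peaks alone, 3 lists passed, the ribosomal protein, cuticle protein and receptor genes. The Polycomb and Trithorax group (ratio 2.11, Fisher's exact test, adjusted p = 0.175), cell cycle (1.85, adjusted p = 0.196), neural (0.191, adjusted p = 0.179) and protease lists (0, adjusted p = 0.0525, all by Fisher's exact test) were not called with them. The cell cycle and protease differences were no smaller than in the full set, and fewer genes carried a peak.

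The other signalling and developmental lists did not differ from other genes in this test. The EGFR pathway had peaks at 10 of 21 genes (47.6%, Fisher's exact test, adjusted p = 0.169), highest at spi (988), Raf (602), Ras85D (499) and Krn (418). It passed when summits anywhere in the gene counted (ratio 1.96, Fisher's exact test, adjusted p = 0.00785), a count that grows with gene length. With summits within 1000 bp of a TSS, the ratio to matched random lists was 1.26 (permutation adjusted p = 0.576). The Wnt pathway had 5 of 22 (sgg 871, nkd 334, Wnt6 164 and Axn 139), the Hedgehog pathway 4 of 13 (disp 151, smo 137, ptc 136 and fu 135), the BMP pathway 4 of 18 (Mad 528, brk 300, shn 229 and put 139) and the JAK-STAT pathway 3 of 11 (Stat92E 226, Ptp61F 178 and Socs36E 118). With summits counted anywhere in the gene or within 1000 bp, the Wnt and BMP lists were higher than other genes (ratios 1.75 and 1.83, Fisher's exact test, adjusted p = 0.0283 for each), a count that grows with gene length. Against random lists matched on gene length and number of TSSs, with summits within 1000 bp of a TSS, the ratios were 0.593 and 0.560 (permutation adjusted p = 0.251 for each). Segmentation regulators had 3 of 24 (12.5%, Fisher's exact test, adjusted p = 0.162), nanos (348), bcd (309) and oc (111), and were lower with a window of 5000 bp (ratio 0.414, adjusted p = 0.0142). Hox genes and cofactors had 1 of 11 (Antp 116) and mesoderm and muscle regulators 6 of 25 (Poxm 228, tin 197, how 185 and Mef2 161). Epidermis and trachea regulators had 1 of 16 (Ddc 150) and were lower against matched random lists (ratio 0.139, permutation adjusted p = 0.00352) and with a window of 500 bp, where 0 members had a peak (Fisher's exact test, adjusted p = 0.0318). With 0 members they were also lower without replicate 1 (Fisher's exact test, adjusted p = 0.0312) and without replicate 2 (adjusted p = 0.0430), but not without replicate 3 (ratio 0.259, adjusted p = 0.258). Endoderm and blood regulators had 4 of 15 (fkh 383, ush 284, pnt 208 and Pvr 126), and muscle structural genes 3 of 17 (Msp300 1835, sls 314 and Tm1 145). Proteasome subunit genes had 20 of 48 (41.7%, Fisher's exact test, adjusted p = 0.162; Rpn5 697, Rpn6 479, Rpn3 383 and Prosbeta1 354) and were higher with a window of 500 bp (ratio 1.59, adjusted p = 0.0499) and against matched random lists (ratio 1.65, permutation adjusted p = 0.0490). Heat shock protein genes had 5 of 19 (Hsp27 882, Hsp26 413, Hsp83 346 and Hsp68 271).

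**Figure D3:**
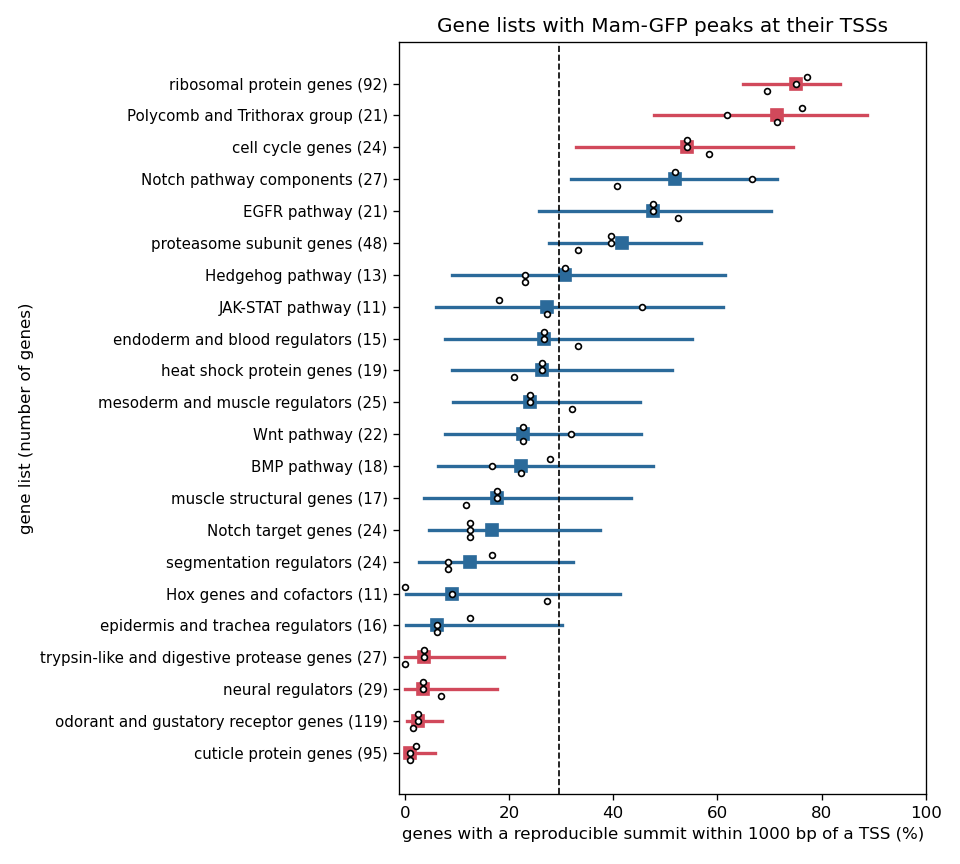
Percent of the genes of each list with a reproducible summit within 1000 bp of a TSS (squares) with exact 95% intervals (lines), and the same share for the 5326 strongest peaks of each replicate (open circles). Lists that differed from other genes are red and the others blue, and the dashed line marks the 29.7% of all protein-coding genes. Ribosomal protein genes stand at 75.0%, Polycomb and Trithorax group genes at 71.4% and cuticle protein genes at 1.05%.

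No difference in signal was called for the 9 lists with enough genes to test. By permutation, 0 passed after adjustment and 1 had an unadjusted p under 0.05, with ratios to other genes from 0.699 for the Wnt list to 1.48 for heat shock protein genes. That list was the ribosomal protein genes, with a median signal of 286 against 233 for other genes with a peak (permutation p = 0.0479, adjusted p = 0.431). For the Notch pathway components the medians were 226 and 235 (permutation p = 0.854, adjusted p = 0.854). The most summits in a gene and 5000 bp around it were 16 at CG1677 (X, 7281089 to 7405797), 15 at sbb (2R, 18278198 to 18357296), 13 at Raf (X, 2295466 to 2343870), 13 at ush (2L, 476220 to 540560) and 12 at CHES-1-like (X, 7682338 to 7709385). These genes are long, with a median of 64341 bp against 2165 bp for protein-coding genes, and their densities of 1.19 to 3.24 summits per 10 kb compare with 0.389 over the genome. High densities are built into a choice by number of summits, and no test was made of them. Genes can overlap, and the span of CG1677 contains brk, so the same summit can count for several genes.

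Of the 19 motifs, 2 stood out at the summits, the DNA replication-related element (DRE), bound by DREF and BEAF-32, and the site of the promoter factor M1BP. DRE sites (TATCGATA) lay within 100 bp of 310 summits, 5.82% against 0.732% of paired windows (ratio 7.95, exact McNemar test, adjusted p = 1.2e-52), with a ratio of 8.08 ± 1.27 (SD, n = 3) in the replicates. M1BP sites (GGTCACACT) lay near 134 summits, 2.52% against 0.319% (ratio 7.88, exact McNemar test, adjusted p = 3.7e-23), with 8.52 ± 3.42 in the replicates. The reversed motifs were found at 0.789% and 0.601% of summits, and these reversed motifs still had ratios of 3.23 and 3.56 to their paired windows. Both sites belonged to promoters. DRE was present at 10.2% of promoter summits and 0.579% of other summits (Fisher's exact test, adjusted p = 5.45e-61), and M1BP at 4.47% and 0.165% (adjusted p = 1.06e-28). Away from promoters neither exceeded its paired windows, with ratios of 0.737 for DRE and 1 for M1BP. Against the weaker pooled peaks the ratios were 3.07 for DRE and 2.12 for M1BP (Fisher's exact test, adjusted p = 4.88e-44 and 1.99e-10), and with the 2663 strongest peaks the M1BP ratio was 4.5 (exact McNemar test, adjusted p = 5.8e-06). Promoters held 54.6% of reproducible summits but 26.0% of the weaker pooled summits, a ratio of 2.10. The peaks were not matched on this share, and promoters without a peak were not compared. Whether these sites mark the reproducible peaks or promoters in general therefore cannot be told.

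The Su(H) site (YGTGRGAA), the sequence bound by the DNA-binding partner of Mam, lay near 124 summits, 2.33% (95% interval 1.94% to 2.77%) against 1.86% (1.51% to 2.26%) of paired windows. This difference did not pass the test (ratio 1.25, exact McNemar test, adjusted p = 0.172). The ratio was 1.18 ± 0.0389 (SD, n = 3) in the replicates, and the reversed motif was at 1.80% of summits. With the paired window on the other side of the summit, an alternative chosen after the data were seen, the ratio was 1.12 (exact McNemar test, adjusted p = 0.544), and with the window 500 bp away it was 0.905 (adjusted p = 0.479). Peaks with a Su(H) site were not stronger. Their mean rank, counted from the strongest, was 2882 against 2658 for the others, a difference of 224.2 ranks (permutation p = 0.108), which was 32.3 to 131 ranks when a replicate was left out.

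The proneural E-box (GCAGSTG), bound by basic helix-loop-helix factors of neural precursors, was less frequent at summits than in paired windows, 4.66% against 8.58% (ratio 0.543, exact McNemar test, adjusted p = 2.94e-15), and 0.551 ± 0.0359 (SD, n = 3) in the replicates. Its reversed sequence was lower to a similar degree, with a ratio of 0.590. The Twist and Snail E-box (ratio 0.779, adjusted p = 0.00025), the Runt site (0.791, adjusted p = 0.0242) and the GAGA repeat (0.789, adjusted p = 0.0393, all by the exact McNemar test) were also lower. The GAGA repeat was higher, with a ratio of 1.25, when windows reached 250 bp (exact McNemar test, adjusted p = 0.000255). Its call was lost with the paired window on the other side (0.926, adjusted p = 0.584), without repeat-masked peaks (0.926, adjusted p = 0.550), with merged summits (0.835, adjusted p = 0.159, all by the exact McNemar test). It was also lost without replicate 2 or 3, where fewer peaks were counted and the ratios stayed at 0.775 and 0.799 (exact McNemar test, adjusted p = 0.0605 and 0.110), and with windows of 50 bp the ratio was 0.5 (adjusted p = 2.04e-05). The Runt call was lost with windows of 250 bp (0.923, exact McNemar test, adjusted p = 0.210), with the 2663 strongest peaks (0.811, adjusted p = 0.203) and without replicate 2 (0.848, adjusted p = 0.212), and the Twist call without promoter summits (0.894, adjusted p = 0.570). Sites of Caudal (ratio 1.26, adjusted p = 3.65e-11), of homeodomains (1.28, adjusted p = 3.68e-06) and of the TCF factor Pangolin (1.19, adjusted p = 0.0267, all by the exact McNemar test) were higher, but their reversed sequences gave ratios of 1.62, 1.35 and 1.44. The TCF call was lost without each of the 3 replicates in turn (ratios of 1.14 to 1.17), with the paired window on the other side (1.11, exact McNemar test, adjusted p = 0.167) and in 5 other alternatives. The Caudal and homeodomain calls were lost without promoter summits (1.03 and 1.07, exact McNemar test, adjusted p = 0.756 and 0.668), and the homeodomain call also with windows of 50 bp. The summits were richer in A and T, with a G+C content of 37.2% against 43.2% in paired windows. The other 9 motifs besides Su(H) did not pass, with ratios of 0.769 for Zelda, 1.31 for Grainy head, 1.04 for the CATATG E-box, 1.37 for Dorsal, 1.04 for GATA factors, 0.991 for Stat92E, 1.39 for Mef2, 1.23 for the TATA box and 0.991 for the initiator. The TATA box was higher with the paired window on the other side (1.57, adjusted p = 0.0166), 500 bp away (1.75, adjusted p = 0.00208) and without repeat-masked peaks (1.61, adjusted p = 0.0104, all by the exact McNemar test), and Zelda was lower with windows of 250 bp (0.805, adjusted p = 0.00920). Against the weaker pooled peaks, the CATATG E-box (1.16, adjusted p = 0.0199) and GATA sites (1.22, adjusted p = 0.0208, both by Fisher's exact test) were higher.

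**Figure D4:**
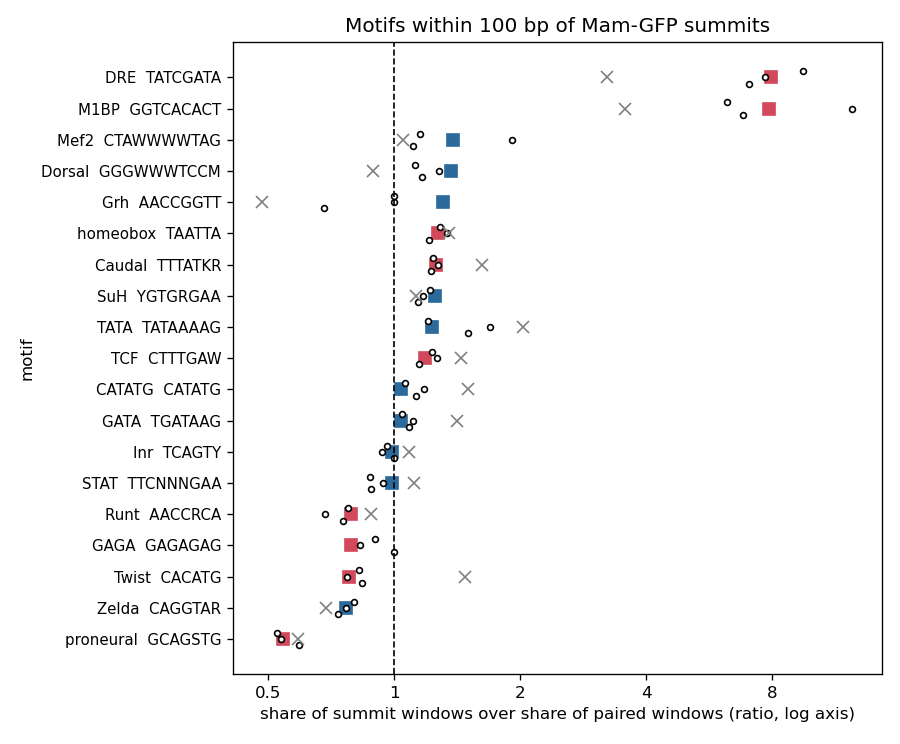
Ratio of the share of summits with each motif within 100 bp to the share of paired windows (log axis) for the reproducible peaks (squares, red where the test passed and blue where it did not), for the 5326 strongest peaks of each replicate (open circles) and for the reversed motif in the reproducible peaks (grey crosses). DRE and M1BP lie near 8 and the other motifs between 0.543 and 1.39.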

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

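Most values kept their direction and their side of the threshold. Of 670 values recomputed under an alternative, 559 did so or moved by less than the spread, 33 lost and 17 gained a call, 51 changed direction and 10 moved by more than the spread. Each value had a single label. The 33 include falls in the number of lists or motifs that passed. The 51 include ratios of exactly 1 and values that also lost or gained a call. Support was 88.9% with the dm3 lists, and the promoter ratio was 5.03 against the G+C-matched background. With summits closer than 500 bp merged, the ratio was 4.72 for promoters, 0.561 for Notch target genes and 1.75 for Notch pathway components. The other alternatives were set before the data were examined. The background matched on G+C content, the merged summits and the paired window on the other side were chosen after the data were seen. Unless stated, the cause of a change was not tested. Depth is unknown from peak lists, so how it limits weak peaks cannot be given.

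Support of the reproducible peaks (88.8%) was 76.5% with a reciprocal overlap of 50%, 85.7% with summits within 100 bp, 51.8% with the 2663 strongest peaks per replicate, 99.0% with 10652, 99.8% with whole replicate lists and 99.8% for the 2663 strongest reproducible peaks. Shorter and longer lists change it by construction. Pairwise overlap (81.7%) was 72.9% with a reciprocal overlap of 50%, 76.0% with summits within 100 bp, 72.9% with 10652 peaks and 79.4% to 84.9% when a replicate was left out. The number of lists that passed fell from 7 to 3 with the 2663 strongest peaks, where fewer genes carry a peak, and the number of motifs from 9 to 3 without promoter summits. When a replicate was left out, the ratio was 1.67 to 1.83 for Notch pathway components, 0.170 to 0.345 for Notch target genes, 0.628 to 1.16 for the Hedgehog list, 0.371 to 0.753 for the JAK-STAT list, 0 to 0.376 for Hox genes and cofactors, 0 to 0.259 for epidermis and trachea regulators and 1.01 to 1.10 for endoderm and blood regulators. In these runs it was 0.990 to 1.01 for arm 2R, 0.993 to 1.00 for arm 3R and 0.867 to 1.08 for the Grainy head site.

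Directions turned mostly for results that passed no test. With the 2663 strongest peaks the ratios were 1.01 for arm 2R, 0 for the Hedgehog list, 1.11 for endoderm and blood regulators, 1.17 for heat shock protein genes, 0.927 for GATA sites, 0.857 for Grainy head sites and 1.09 for the signal of Notch pathway components. Against TSS shares arms 2L and 3L had ratios of 0.948 and 1.04. With a TSS window of 5000 bp the ratios were 1.11 for the BMP list, 1.19 for mesoderm and muscle regulators, 1.19 for endoderm and blood regulators, 1.15 for heat shock protein genes and 1.08 for the signal of Notch pathway components. With summits counted in the gene or within 1000 bp they were 1.75 for the Wnt list, 1.83 for the BMP list, 1.32 for mesoderm and muscle regulators, 1.03 for epidermis and trachea regulators, 1.10 for endoderm and blood regulators and 1.01 for heat shock protein genes. Against matched random lists the Hedgehog ratio was 0.911. With motif windows of 50 bp the Stat92E ratio was 1.10. With 250 bp it was 0.978 for CATATG, 1.25 for GAGA and 1.02 for the initiator, and the rank difference of Su(H) peaks was -42.1. With paired windows 500 bp away the ratios were 0.905 for Su(H), 0.739 for Grainy head, 0.684 for Dorsal and 1.07 for Stat92E. With the window on the other side they were 0.810 for Grainy head and 0.839 for Dorsal. Against the weaker pooled peaks they were 0.789 for Dorsal and 1.13 for Stat92E. Dorsal had a ratio of 1 without repeat-masked peaks, and Grainy head 0.750 with merged summits. Without promoter summits the ratios were 0.737 for DRE, 1 for M1BP, 1 for Grainy head, 0.385 for Dorsal and 1.04 for Zelda.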

Other observations

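All tests in this part were chosen after the main results had been seen, the tRNA test away from promoters after the first tRNA result and the tests of the octamer after the octamer counts. For the tests of the 3 patterns weighed here the expected outcome was written before the value was computed, and for the other values none was written. Genes outside the protein-coding set also carried reproducible summits. Within 500 bp, a summit lay at 7 of 32 snRNA genes (21.9% against 3.76% of random positions, Fisher's exact test, adjusted p = 0.000313), at 22 of 290 tRNA genes (7.59% against 3.83%, adjusted p = 0.00612) and at 386 of 3261 ncRNA genes (11.8% against 7.09%, adjusted p = 1.02e-19). Neighbouring genes were counted singly, so a summit could count for several of them. Only tRNA genes were also compared away from protein-coding TSSs, as given below. For the other kinds, nearness to protein-coding promoters was not weighed. The share at snoRNA genes was 4.83% against 4.19% (Fisher's exact test, adjusted p = 0.634), and annotated transposable elements were lower, at 2.00% against 7.96% (adjusted p = 7.27e-81). How much of the transposable elements could be mapped is not given in the sources used here.

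In the pooled list, which includes peaks below the reproducibility threshold, 26 of 27 Notch pathway components had a summit within 1000 bp of a TSS (96.3% against 58.8% of other genes, Fisher's exact test, adjusted p = 8.32e-05). The excess was not particular to them, since ribosomal protein (95.7%), cell cycle (91.7%), Polycomb and Trithorax group (90.5%) and Wnt pathway genes (86.4%) also passed this test (Fisher's exact test, adjusted p = 7.7e-15, 0.00228, 0.00917 and 0.0204). Of the Notch target genes 18 of 24 did (75.0% against 58.8%, Fisher's exact test, adjusted p = 0.234), and 14 of the 18 had only weaker peaks. In the E(spl) complex, the weaker peaks nearest to E(spl)mgamma-HLH (signal 48.4), E(spl)m2-BFM (74.5) and E(spl)m8-HLH (38.5) each had a Su(H) site within 100 bp of the summit, as did a peak 1086 bp from the TSS of E(spl)mbeta-HLH (43.0). These were 4 of the 18 weaker summits in the complex, the other 14 had no site, and over all weaker pooled peaks the share with a site was 2.27%. Among reproducible peaks, those with an M1BP site were weaker than the rest, with a mean rank of 3190 against 2650 (permutation p = 7e-05), while DRE sites showed a rank difference of 32.7 (permutation p = 0.717). Octamers were also counted within 100 bp of promoter summits. A minimum of 20 summits was set for testing an octamer, which can favour those higher at summits. Of 8185 octamers tested, 1581 were higher at summits and 62 lower after adjustment. The higher ones were led by ATCGATAG and TATCGATA, which overlap the DRE, and by CAACACTG, found at 7.23% of promoter summits against 0.688% of paired windows. Overlapping octamers were counted singly, and the lower G+C content of summits was not weighed in these counts.

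The first pattern was that reproducible peaks favoured promoters and, among the lists, ribosomal protein and Polycomb and Trithorax group genes, with no called excess of Su(H) sites or of Notch target genes. Random positions of the same G+C content were promoters in 10.9% of cases, against 54.6% of summits (ratio 5.03). G+C content therefore did not account for the promoter share, and it was not weighed for the gene lists. DRE sites were 8.86 times as frequent at summits as at these positions (Fisher's exact p = 1.12e-113). G+C content therefore did not account for the DRE excess either (5.82% of summits against 0.657% of matched positions). DRE sites lay mostly at promoters (10.2% of promoter summits against 0.579% of others). The matched positions were not matched on location, so the excess may follow from location. A candidate explanation is that DNA of strongly transcribed genes was enriched without binding by Mam, for which tRNA genes, transcribed by RNA polymerase III, were the test. Their share with a summit was 1.98 times that of random positions (7.59% against 3.83%, Fisher's exact p = 0.0049). For tRNA genes with no protein-coding TSS within 2000 bp the share was lower, 5.45% (9 of 165). It was 3.91 times that of random positions which also had no such TSS within 2000 bp (1.39%, Fisher's exact p = 0.00153). This explanation therefore stays open. These p-values treat the tRNA genes as independent, although neighbouring genes can share a summit. Dilution of Notch-dependent binding in whole embryos of mixed stages also stays open, since weaker pooled peaks had a Su(H) ratio of 1.11 (exact McNemar p = 0.143), which neither shows nor excludes an excess, and no biological explanation was tested.

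The second pattern was the near lack of summits in coding sequence. Random positions of the same G+C content were coding in 5.09% of cases rather than 14.3%, so base composition may account for part of it, but the ratio of summits to matched positions was still 0.0332 (Fisher's exact p = 2.04e-92). Without a promoter class, so that summits near a TSS could count as coding, 27 summits were coding and the ratio was 0.0296. The ratio was then 0.275 for the 3' UTR, 1.02 for introns, 1.40 for intergenic sequence and 2.78 for the 5' UTR. Neither explanation therefore accounts for the whole pattern. Weaker pooled peaks were coding in 11.0% of cases, and no biological explanation was tested.

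The third pattern came from the count of octamers within 100 bp of summits, with paired windows 1000 bp away and the same minimum of 20 summits. Away from promoters, 397 of 6511 octamers tested were higher and 29 lower. The higher ones were led by CACTGAGA, the first of the sorted list and chosen for that reason. It was found at 154 of 2420 summits (6.36% against 0.496%, exact McNemar test, adjusted p = 2.46e-29) and at 5.46% ± 0.140 (SD, n = 3) of such summits of the replicates. The lowest ratio among the replicates was 11.8, so no single replicate carried it, and the ratio to random positions of the same G+C content was 9.44 (Fisher's exact p = 1.19e-71). Of 162 such sites, 60.5% were soft-masked as repeats (95% interval 52.5% to 68.1%), against 18.7% of all bases in these windows. The sites lay a median of 62.5 bp from the summit, within the 100 bp searched. This distance was not compared with random placement and does not show that the sites mark the summit. Repeated sequence is a candidate source of these sites, although soft-masking does not tell interspersed from simple repeats, 31 of the 5326 peaks were over 50% soft-masked and transposable elements held fewer summits than random positions. That last comparison cannot decide, since how much of the transposable elements could be mapped is unknown. Whether Mam or another protein binds these sites was not tested, and no biological explanation was tested.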
